A study of Mus musculus with 12 samples.

How the data were processed

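Dissociated retinas of WT, DKO and C198R mice at 1 and 4 months were profiled in 12 libraries, 2 per group. Per the labels' protocols, retinas of males and females were pooled by genotype, single-cell suspensions were made by a protocol meant to keep cones alive, and libraries were prepared on the 10x Chromium platform. Per the submitters' processing notes, reads were processed with Cell Ranger 6.1.2 and the genome build was GRCm38; the annotation release is not given in the sources used here. The deposited values are whole-number UMI counts per gene and barcode, filtered to called cells by the authors, with no normalization. Groups and replicate numbers were taken from the labels. Replicates were compared by a chi-square test of their counts over genes, which gave 6.46 to 85.9 per gene, so none differed as little as sampling noise would allow and none was counted as a copy.

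Cells were kept with at least 200 genes and at most 25% mitochondrial UMIs. Of 31925 barcodes, 944 fell short of the first limit and 2107 passed the second. Doublets were called per library with Scrublet in scanpy 1.11.5 (expected rate 0.06) and removed: 399 cells, 1.38% of those tested and 0.0890% to 4.86% per library. In 6 libraries under 0.5% were marked, and whether doublets were missed there was not tested. The remaining 28475 cells, 176 to 6076 per library, were clustered over all libraries on 2000 variable genes without the cone phototransduction list, with 30 principal components, a graph of 15 shared neighbours and Leiden clustering at resolution 1 (igraph 0.11.9). The run used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.

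Of 42 clusters, 33 were named from markers fixed before the data were examined, as "-like" classes. A cluster took the class with the highest mean marker fold among those with at least 3 markers, and more than 1 in 3 of the class's markers, present in at least 5% of its cells and raised by at least 1 log2 over all other cells (offset 10 CPM). It stayed unnamed where none qualified, where another class had more markers among its top 10 genes, where the class ranked second also had enough raised markers, at least 50% of its own, with a mean fold above 1 log2 (pairs of rod and cone bipolar classes excepted), or where its cells held under 1 in 3 of their library's median UMIs with no marker among the top genes. The naming rule was adjusted once after a first pass, in which free hemoglobin RNA had named clusters of other cells as red blood cells: only a class with enough raised markers could then give a name. The 9 unnamed clusters held 2567 cells: 4.60% of WT 1M, 10.1% of WT 4M, 8.19% of DKO 1M, 13.6% of DKO 4M, 8.51% of C198R 1M and 8.22% of C198R 4M cells. The 2 cone-like clusters were named from 11 markers other than the opsins, Pde6h among them.

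Counts were summed per library and class, and libraries with at least 10 cells of the class entered a fit. For cones these were 9 libraries, of 10 to 273 cells and 49239 to 1924990 UMIs, since WT 1M replicate 2, DKO 4M replicate 2 and C198R 4M replicate 1 held 8, 5 and 5 cone-like cells. WT 1M, DKO 4M and C198R 4M thus each rest on 1 library, assumed to vary like the other groups. Rod genes gave 0.876% to 1.46% of the UMIs of these 9 cone sums. Rod fits held 12 libraries and Müller glia fits 11. Genes were filtered with filterByExpr, scaled with TMM and tested with edgeR 4.0.16 by the quasi-likelihood F-test with 1 mean per group (R 4.3.3). Adjusted p values are Benjamini-Hochberg values from that test, called under 0.05, and the SE of a log2 fold change is its size over the square root of F. Values described as adjusted over the list alone use the members of 1 list. CPM values are counts over all UMIs of the class in the library. Intervals are 95% and cover counting error only. A fold against a group at 0 counts is a lower bound set against 3 counts over the group.

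Contrasts were each mutant against WT at each age, DKO against C198R at each age, 4M against 1M in each genotype, and the difference of each mutant's age effect from that of WT. Lists of genes fixed before the data were examined were tested with camera in limma 3.58.1 (preset inter-gene correlation 0.01, at least 3 members), over 22 lists and 11 contrasts: cone phototransduction, phototransduction shared by rods and cones, retinoid metabolism, outer segment and connecting cilium, photoreceptor transcription factors, photoreceptor synapse, unfolded protein response, proteasome, heat shock proteins, immediate early genes, mitochondrially encoded and nuclear-encoded respiratory chain, glycolysis, cell death, antioxidant and metal response, autophagy and lysosome, interferon and antigen presentation, ribosomal proteins, rod genes, Müller glia genes, bipolar cell genes and sex-linked genes. A list of retinal stress genes had fewer than 3 members measured in cones and gave no test. Cone-enriched genes were those above 1 log2 with adjusted p under 0.05 in cone-like against rod-like sums of 3 WT libraries, with library as a block (10586 genes tested, 1285 chosen, all 11 cone phototransduction genes among them). The share of cone-like cells was compared by an exact permutation test over 4 libraries against 4.

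Genes were named by a rule fixed before the data were examined: among genes past the threshold with a mean log2 CPM of at least 5 and every library of 1 group beyond those of the other, up to 8 with the largest rise and 8 with the largest fall for each mutant against WT and each mutant's age effect, leaving out predicted-gene symbols, plus up to 4 passing members per list, and up to 4 each way for other contrasts and cell types. Cone-enriched and shared genes beyond that rule were named after their values were seen. Some genes that the rule names are not reported here, while counts cover all genes. Gene locations are from the GENCODE mouse release 21 annotation of GRCm38, which matched 7037 of the 7040 genes tested in cones by identifier. UMI counts of overlapping or antisense genes and of near-identical copies may be split or lost by the counting.

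The number of barcodes and the UMIs per barcode split the libraries into 3 with many and 9 with few, a technical split seen after the data were examined. DKO against WT, C198R against WT and DKO against C198R at 1M and the age effect of DKO lie within the libraries of few barcodes, C198R against WT at 4M within those of many, and the other cone contrasts cross the split. Alternatives fixed beforehand were RLE size factors, DESeq2 1.42.0, no filter on low counts, a replicate block, each library left out in turn, doublets kept, no mitochondrial maximum, clustering with all variable genes, Leiden resolution 2, a rod gene covariate, other minimums of cells (30 or 1), an estimated inter-gene correlation, a threshold of 2 log2 for cone-enriched genes and shares of photoreceptor-like cells. Fits within a barcode group or with a term for it (in cones with a minimum of 1 cell), and the cone phototransduction list without the opsins, were added after the data were seen.

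The tests were run on simulated data with 200 genes changed per group, 5 times. In the 7040 cone genes edgeR found 11.0% of 2-fold and 45.2% of 4-fold changes for DKO against WT at 1M, with 2.77% of its calls wrong. It found 22.6% and 57.8% for DKO at 4M with 2.90% wrong, 11.4% and 41.6% for C198R at 1M with 2.93% wrong, and 70.2% and 93.8% for C198R at 4M with 5.42% wrong. Most 2-fold changes at 1M would be missed. In the 9958 rod genes 5.48% to 16.7% of edgeR's calls were wrong, and in the 13553 Müller glia genes 5.98% to 12.1%. Of 440 simulated list tests 6 were called. No rate here was tested for barcode effects or correlated genes. Horizontal, lens and other minor classes were not tested.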

Results

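Single-cell RNA sequencing was carried out on dissociated mouse retinas of 3 genotypes at 1 and 4 months of age (1M and 4M), with 2 libraries in each of the 6 groups. The genotypes were wild type (WT) and a pair of models of blue cone monochromacy, an inherited loss of cone function: DKO, which lacks both cone opsin genes, and C198R, which carries a missense change in Opn1mw on a background without Opn1sw. The purpose stated for the series was to compare gene expression in cone photoreceptors between the genotypes at each age, and to find cone genes that stayed level or rose from 1 to 4 months in the mutants. The 12 libraries held 31925 barcodes and 155704525 UMIs. Depth was uneven. The 2 WT 4M libraries and C198R 4M replicate 2 held 5604 to 6993 barcodes with medians of 3801.5 to 4241 UMIs. The other 9 held 209 to 2379 barcodes with medians of 823 to 3014 UMIs. These are called libraries with many and with few barcodes. WT 1M replicates 1 and 2 held 7206745 and 3715614 UMIs, and WT 4M 32656982 and 40954784. For DKO 1M the totals were 3543102 and 7505620, and for DKO 4M 6877915 and 1952895. For C198R 1M they were 6877891 and 11805305, and for C198R 4M 576155 and 32031517. The labels do not say that the libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

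Most retinal classes were recovered in the 28475 cells kept. Rod-like cells made up 46.5% of them, Müller glia-like cells 16.6% and cone-like cells 3.25%, or 926 cells. Both cone-like clusters had Pde6h, Pde6c, Gnat2 and Gngt2 among their top 10 genes, genes of the cone phototransduction cascade. Rod bipolar-like cells numbered 2800, cone bipolar-like cells 1612, microglia-like cells 629, endothelial-like cells 571 and amacrine-like cells 386. Of all cells 9.01% stayed unnamed.

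Cones were a small share of every library, and the share did not differ detectably between genotypes. The mean share of cone-like cells was 2.87% ± 2.10 in WT, 2.0% ± 1.17 in DKO and 2.53% ± 1.35 in C198R (SD, n = 4 libraries each, both ages). DKO differed from WT by -0.871 percentage points (two-sided exact permutation p = 0.514) and C198R by -0.348 (two-sided exact permutation p = 0.771). With 70 splits the smallest possible exact p is 0.0286. Among the libraries with few barcodes, WT was at 1.15% ± 0.768 (n = 2). There DKO lay 0.854 points above it (exact permutation p = 0.467, smallest possible 0.0667) and C198R 0.891 points above it (exact permutation p = 0.4, smallest possible 0.1). Both differences from WT thus had the opposite sign there, and the batch with many barcodes held no DKO library. The C198R difference also changed sign without WT 4M replicate 1 (0.422), WT 4M replicate 2 (0.0327) or C198R 1M replicate 1 (0.253). The DKO difference ranged from -1.63 to -0.101 points as each library was left out.

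**Figure D1:**
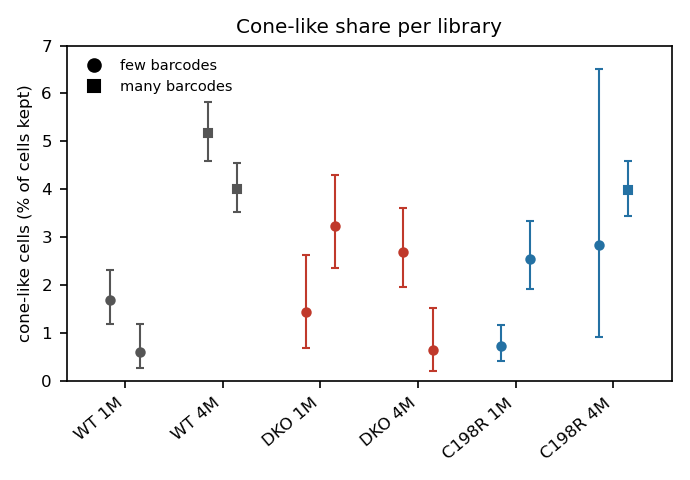
Cone-like cells as a percent of the cells kept, per library and group, with exact 95% Clopper-Pearson intervals that cover counting error only. Shares range from 0.607% in a WT 1M library to 5.18% in a WT 4M library, and the libraries of a group differ by more than the genotype means.

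The targeted genes were examined first, in every library. Opn1sw, the short-wavelength cone opsin (ENSMUSG00000058831, chromosome 6, 29376671 to 29388468, minus strand, GRCm38), stood in the cone-like cells of the WT libraries at 3878 and 5448 CPM (counts scaled to the library total) at 1M and 5347 and 4642 CPM at 4M. In DKO cones it was at 122 and 99.9 CPM at 1M and 88.9 and 370 CPM at 4M. In C198R cones it was at 278 and 85.2 CPM at 1M and, at 4M, at 48.4 CPM (1 count, 95% counting interval 1.22 to 269) and 99.3 CPM. Rod-like cells, which should lack the gene, held at most 21.8 CPM in any group.

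Opn1mw, the medium-wavelength cone opsin (ENSMUSG00000031394, chromosome X, 74127464 to 74150760, plus strand), was lower in DKO than in WT cones and close to the WT level at 1M in C198R cones. WT cones averaged 3117 ± 236 CPM at 1M and 4613 ± 95.7 at 4M (SD, n = 2 libraries per group), DKO cones 1117 ± 201 and 1208 ± 806, and C198R cones 3006 ± 165 and 2766 ± 1039. The fitted changes in DKO were a fall by 1.46 ± 0.24 on the log2 scale at 1M (log2 fold change ± SE, adjusted p = 3.27e-05) and a fall by 1.39 ± 0.23 at 4M (adjusted p = 2.63e-05). The 3' tags counted here can lie outside a deleted part of a gene, so the Opn1mw counts do not check the DKO labels, and a point change cannot be seen in them. Rod-like cells held at most 9.10 CPM of Opn1mw in any group.

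**Figure D2:**
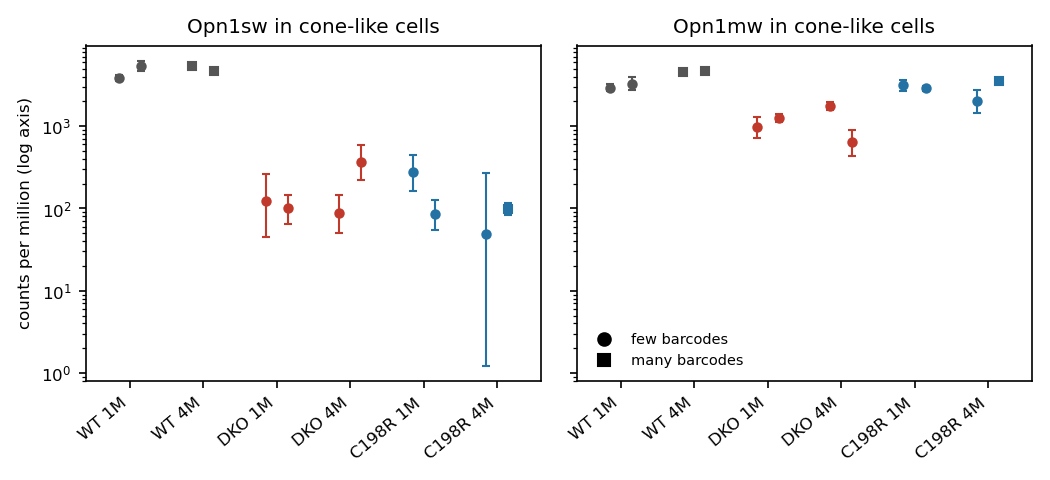
CPM of Opn1sw and Opn1mw in cone-like cells, 1 point per library on a log axis, with 95% Poisson intervals that cover counting error only; squares mark the libraries with many barcodes. Opn1sw lies at 3878 CPM or above in the WT libraries and at 370 CPM or below in the mutant ones, while Opn1mw in C198R lies between 2031 and 3500 CPM and in DKO between 638 and 1778 CPM.

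The first comparison asked how cones without both opsins differed from WT cones at 1 month, with 2 DKO libraries against 1 WT library, since WT 1M replicate 2 held 8 cone-like cells. Few genes passed. Of 7040 genes tested, 4 rose and 25 fell in DKO, 3 of them with predicted-gene names. Of the 4 that rose, Me3 and a gene with a predicted name lay outside the naming rule. The others were Trhde, an ectoenzyme that degrades thyrotropin-releasing hormone (ENSMUSG00000050663, chromosome 10, 114398823 to 114802307), up by 1.85 ± 0.30 log2 (adjusted p = 3.27e-05), and Akap6, an anchoring protein for protein kinase A (ENSMUSG00000061603, chromosome 12, 52699383 to 53155599), at 1.29 ± 0.29 (adjusted p = 0.00991). Opn1sw fell by 5.33 ± 0.31 (adjusted p = 9.82e-26). The receptor tyrosine kinase gene Alk fell by 2.52 ± 0.53 (adjusted p = 0.00507), Wdr95 by 2.44 ± 0.50 (adjusted p = 0.00372), the phosphodiesterase gene Pde10a by 2.44 ± 0.59 (adjusted p = 0.0242). Arhgap31, a GTPase-activating protein, fell by 3.02 ± 0.77 (adjusted p = 0.0413). Ralyl, at 3 counts against 19, had a DKO to WT ratio of 0.083 (95% counting interval 0.0157 to 0.282, adjusted p = 0.00803), and Hsd17b12, at 3 counts against 17, a ratio of 0.0927 (0.0174 to 0.321, adjusted p = 0.0205).

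Among the lists fixed beforehand, the cone phototransduction list stood lower in DKO at 1M, with a median of -0.30 log2 over its 11 measured members (camera adjusted p = 5.05e-07). The list holds both targeted genes. They were the 2 members that fell, 3 fell when adjusted over the list alone, and the list had adjusted p = 0.628 with an estimated correlation. Without the targeted genes, a test chosen after the data were seen, the 9 other members had a median of -0.02 (adjusted p = 0.461). The mitochondrially encoded respiratory chain genes had a median of -0.52 over 13 members (adjusted p = 9.29e-20, adjusted p = 0.628 with an estimated correlation). In that list mt-Co1, a cytochrome c oxidase subunit, fell by 0.93 ± 0.24 (adjusted p = 0.0413), and 4 members fell when adjusted over the list alone. The rod gene list had a median of -0.80 over 15 members (adjusted p = 0.0199, adjusted p = 0.808 with an estimated correlation). Adjusted over the list alone, 3 members fell. No member of the nuclear-encoded respiratory chain list passed, over all genes or adjusted over the list alone, and its median of 0.10 over 72 members gave adjusted p = 0.0195 (adjusted p = 0.758 with an estimated correlation). The 6 bipolar cell genes had a median of 1.12 (adjusted p = 0.0444, adjusted p = 0.631 with an estimated correlation), with 0 called over all genes and 1 rising when adjusted over the list alone. Outside these lists Impg1, a proteoglycan of the interphotoreceptor matrix (ENSMUSG00000032343, chromosome 9, 80313330 to 80465481), fell by 1.32 ± 0.31 (adjusted p = 0.0205). DESeq2 called 2 genes. Both groups had few barcodes. With only such libraries 9 genes passed, all among the 29, with Opn1sw at -5.30, Opn1mw at -1.48 and Trhde at 1.86. Without DKO 1M replicate 2 the count was 13, and without WT 4M replicate 1 or replicate 2, which enter the shared estimate of spread, it was 18 and 18. A group's sole library, here WT 1M replicate 1, cannot be left out of its own comparisons. Of the genes named here, Trhde, Opn1sw and Opn1mw kept their call with each of the 8 others left out. Akap6 lost it without either WT 4M library, at 1.38 in each. The others lost it without DKO 1M replicate 2, where Alk was at -1.11, Pde10a at -1.07, Hsd17b12 at -1.57 and Arhgap31 at -9.22, a fitted value that is no bound. Of these, Pde10a, Impg1, Arhgap31 and mt-Co1 also lost it without either WT 4M library, and Arhgap31 (-2.73) and mt-Co1 (-0.85) without DKO 1M replicate 1.

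At 4 months, 71 genes rose and 63 fell in DKO cones against WT cones (134 of 7040, 11 with predicted-gene names), with 1 DKO library against 2 WT libraries. Me3, a mitochondrial malic enzyme (ENSMUSG00000030621, chromosome 7, 89632392 to 89854359), held 30 counts in DKO against 4 in WT and rose by 7.02 ± 0.68 log2 (adjusted p = 2.63e-13). Trhde rose by 2.93 ± 0.20 (adjusted p = 1.1e-21), the axon guidance receptor gene Robo2 by 2.41 ± 0.45 (adjusted p = 0.000257) and the kinesin gene Kif4 by 2.31 ± 0.30 (adjusted p = 2.49e-08). Lrmda rose by 2.05 ± 0.45 (adjusted p = 0.0034), the splicing regulator Rbfox1 by 1.96 ± 0.43 (adjusted p = 0.00332) and Lars2, the mitochondrial leucyl-tRNA synthetase, by 1.94 ± 0.20 (adjusted p = 3.07e-12). Opn1sw fell by 5.82 ± 0.35 (adjusted p = 3.79e-24). Arhgap31 had 0 counts in DKO and was at least 3.33-fold lower against a floor of 3 counts (adjusted p = 0.0135). On the same floor Map1lc3a was at least 3.28-fold, Lman2l at least 2.79-fold, Tvp23b at least 2.53-fold and S100a1 at least 2.44-fold lower. Citron kinase, Cit, at 2 counts against 436, had a ratio of 0.0933 (95% counting interval 0.0113 to 0.339, adjusted p = 0.00171), and Spata6, at 1 count against 252, a ratio of 0.0807 (0.00203 to 0.454, adjusted p = 0.0233).

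Genes of the photoreceptor machinery moved in both directions in DKO at 4M. The cone phototransduction list had a median of -0.29 (adjusted p = 5.43e-10, adjusted p = 0.628 with an estimated correlation). Both opsins and Pde6h, the inhibitory subunit of the cone phosphodiesterase (ENSMUSG00000064330, chromosome 6, 136923832 to 136968865), fell, the last by 1.04 ± 0.24 (adjusted p = 0.00749). Adjusted over the list alone, 1 member rose and 3 fell. Without the opsins the 9 other members had a median of -0.28 (adjusted p = 0.00592, adjusted p = 0.672 with an estimated correlation), and Pde6h fell. In the list shared by rods and cones (14 members, median -0.07, adjusted p = 0.00424, adjusted p = 0.628 with an estimated correlation), phosducin, Pdc, fell by 1.14 ± 0.22 and Aipl1, a chaperone of the phosphodiesterase, by 0.89 ± 0.21, and 3 members fell when adjusted over the list alone. In the outer segment list, which did not pass as a set, Impg2 rose by 1.02 ± 0.19 while Impg1 fell by 1.11 ± 0.27 (adjusted p = 0.000211 and 0.0127). Hspa5, the chief chaperone of the endoplasmic reticulum, fell by 1.5 ± 0.34 (adjusted p = 0.00469) and its cytosolic relative Hspa8 by 1.22 ± 0.24 (adjusted p = 0.000468). The heat shock list had a median of -0.48 over 13 members, of which 1 fell, also when adjusted over the list alone (adjusted p = 0.00128, adjusted p = 0.628 with an estimated correlation).

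Further lists were tested in the same comparison. The 76 ribosomal protein genes had a median of -0.67 (adjusted p = 8.32e-21, adjusted p = 0.628 with an estimated correlation). Of them 6 fell, among them Rpl9 by 1.14 ± 0.25 and Rpl10a by 1.34 ± 0.32, and 31 fell when adjusted over the list alone. Of 20 glycolysis genes, with a median of -0.51 (adjusted p = 5.42e-06, adjusted p = 0.628 with an estimated correlation), Pgam1 fell by 1.22 ± 0.27, Pkm by 0.86 ± 0.22 and Aldoa by 0.77 ± 0.21, and 6 fell when adjusted over the list alone. The nuclear-encoded respiratory chain had a median of -0.33, with Uqcrh falling by 1.17 ± 0.31 and no other member passing, over all genes or adjusted over the list alone (adjusted p = 0.00011, adjusted p = 0.631 with an estimated correlation). The mitochondrially encoded list had a median of -0.12 while mt-Atp8 rose by 0.98 ± 0.28, and 2 rose when adjusted over the list alone (adjusted p = 0.0444, adjusted p = 0.837 with an estimated correlation). The rod gene list had a median of -0.60 with 1 member, Gngt1, falling and 4 falling when adjusted over the list alone (adjusted p = 1.11e-05, adjusted p = 0.631 with an estimated correlation). Gng13, a G protein subunit of ON bipolar cells, rose by 1.74 ± 0.46 (adjusted p = 0.0233). The DKO 4M library had few barcodes and both WT 4M libraries had many, so this comparison has no value within a batch. A fit with a term for the barcode group, which rests on the 5 cone-like cells of C198R 4M replicate 1, called 10 genes. There 15 of the genes named for this comparison took the opposite sign, among them Pde6h at 3.06 and every ribosomal and glycolysis gene named here, with Rpl9 at 1.70 and Pgam1 at 2.33, while Opn1sw stood at -3.66, Opn1mw at -0.87, Impg1 at -2.44 and Hspa5 at -1.10. These 4 did not pass there, nor did Trhde (1.89), Kif4 (1.80) or Lars2 (2.34), and Me3 alone of the named genes tested there did. DESeq2 called 19 genes. Without WT 4M replicate 1 or 2 the count of 134 was 16 and 19. Me3, Trhde, Kif4, Lars2, Opn1sw and Opn1mw, among 36 genes that the naming rule took, kept their call with each of 8 libraries left out, all but the sole DKO 4M library. The call ended for 28 without WT 4M replicate 1 and for 26 without replicate 2, while their log2 values moved by at most 1.13 and 1.15 times. Lman2l also lost it without DKO 1M replicate 2 and Tvp23b without C198R 4M replicate 2.

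For C198R against WT at 1 month, with 2 libraries against 1, 3 genes rose and 10 fell. Me3 rose, with 37 counts in C198R against 0 in WT, at least 5.88-fold higher against the 3-count floor (adjusted p = 0.0241), and Akap6 rose by 1.5 ± 0.28 (adjusted p = 0.000812). The third rise and 1 of the falls carried predicted-gene names. Opn1sw fell by 4.99 ± 0.29 (adjusted p = 5.16e-25). Tmsb10, an actin-sequestering thymosin, fell by 1.79 ± 0.27 (adjusted p = 8.53e-06), Osgep, a tRNA-modifying enzyme, by 2.02 ± 0.36 (adjusted p = 0.000603) and Tmlhe, the first enzyme of carnitine synthesis, by 1.48 ± 0.29 (adjusted p = 0.0018). Alk fell by 2.26 ± 0.50, Arid5b by 2.16 ± 0.49, Apbb1 by 1.87 ± 0.40 and Wdr31 by 1.53 ± 0.35 (adjusted p = 0.0194, 0.024, 0.00954 and 0.0277). The cone phototransduction list had a median of -0.04 with only Opn1sw falling and 2 members falling when adjusted over the list alone (adjusted p = 0.00256, adjusted p = 0.628 with an estimated correlation). Without the opsins its test did not pass (median -0.04, adjusted p = 0.715). The rod gene list stood higher, with a median of 0.57, no member called over all genes and 1 rising when adjusted over the list alone (adjusted p = 0.000928, adjusted p = 0.628 with an estimated correlation). The nuclear-encoded respiratory chain had a median of 0.16 with no member called, over all genes or adjusted over the list alone (adjusted p = 0.0152, adjusted p = 0.758 with an estimated correlation). DESeq2 called 2 genes. With only libraries of few barcodes 5 genes passed, all among the 13, with Opn1sw at -4.84 and Me3, Tmsb10 and Osgep among them. Without WT 4M replicate 1 the count was 5, without WT 4M replicate 2 it was 7 and without DKO 1M replicate 2 it was 8. Opn1sw and Tmsb10 kept their call with each of 8 libraries left out, all but the sole WT 1M library, while the other 8 named genes lost it in at least 1 such fit. These were 6 and 4 genes without WT 4M replicates 1 and 2, with values moved by at most 1.04 times. Without C198R 1M replicate 2 they were Akap6, Alk, Osgep, Apbb1 and Wdr31, at 1.47, -2.07, -2.28, -2.57 and -2.43, and Arid5b kept its call at a fitted -10.27. Without replicate 1 they were Arid5b and Wdr31 (-1.85 and -1.36). Without DKO 1M replicate 2 they were Me3, Arid5b and Wdr31, and without C198R 4M replicate 2 it was Me3.

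At 4 months, C198R cones differed from WT cones in 174 genes, 87 up and 87 down, 21 of them with predicted-gene names, in 1 library against 2. Me3 rose by 5.22 ± 0.55 log2 (adjusted p = 8.28e-12), from 4 counts in WT to 64 in C198R. The cadherin gene Cdh12 rose by 1.70 ± 0.14 (adjusted p = 7.53e-17) and the tenascin gene Tnr by 1.57 ± 0.33 (adjusted p = 0.000994). Akap6 rose by 1.55 ± 0.14 (adjusted p = 1.58e-15), Kif4 by 1.47 ± 0.18 (adjusted p = 3.29e-09), Gng13 by 1.49 ± 0.23 and Ldlrad4 by 1.76 ± 0.26. Opn1sw fell by 5.69 ± 0.28 (adjusted p = 4.4e-31) and Cit by 2.31 ± 0.26 (adjusted p = 1.2e-10). The netrin receptor gene Dcc fell by 2.32 ± 0.41, the transcription factor gene Etv5 by 2.31 ± 0.38, Mcf2 by 1.78 ± 0.27, the protocadherin gene Pcdh9 by 1.58 ± 0.24, Klhl33 by 1.57 ± 0.23 and Alk by 1.55 ± 0.22.

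Impg1 fell by 1.44 ± 0.15 (adjusted p = 8.28e-12) and Hspa5 by 1.25 ± 0.16 (adjusted p = 9.01e-09) in C198R at 4M. The unfolded protein response list, 20 members with Hspa5 among them, had a median of -0.26, with 1 falling and, adjusted over the list alone, 2 rising and 3 falling (adjusted p = 0.0444, adjusted p = 0.628 with an estimated correlation). The heat shock list had a median of -0.27, with 0 called over all genes and 5 falling when adjusted over the list alone (adjusted p = 0.000626, adjusted p = 0.628 with an estimated correlation). In the cone phototransduction list only Opn1sw fell, also when adjusted over the list alone. Its median was 0.02, its mean -0.55 and its test pointed down, so that median and test differ in sign (adjusted p = 0.00737, adjusted p = 0.628 with an estimated correlation). Without the opsins it did not pass (median 0.08, adjusted p = 0.671). The mitochondrially encoded list had a median of -0.21 and mt-Nd4l, a complex I subunit, fell by 0.55 ± 0.15, as the sole member also when adjusted over the list alone (adjusted p = 1.86e-06 for the list, adjusted p = 0.631 with an estimated correlation). The nuclear-encoded list had a median of 0.16 with no member passing, over all genes or adjusted over the list alone (adjusted p = 0.0011, adjusted p = 0.631 with an estimated correlation). Of the bipolar cell genes 2 rose, Gng13 and Cabp5, also when adjusted over the list alone, with a list median of 0.18 (adjusted p = 0.0444, adjusted p = 0.631 with an estimated correlation). Single members of lists that did not pass also changed. Nr4a1 fell by 1.49 ± 0.30, Jun rose by 0.89 ± 0.23, and hexokinase Hk2 fell by 0.66 ± 0.15. Gabarapl1 rose by 0.73 ± 0.16, Samd11 rose by 1.00 ± 0.29 and the Y-linked Eif2s3y rose by 0.73 ± 0.21. All 3 libraries had many barcodes. In a fit of these alone the spread came from the 2 WT 4M libraries, so its calls are no check of the 174 and are not given. DESeq2 called 4 genes, a fit with the rod gene ratio as a covariate 11, a fit with a replicate block 32, and one that took any library with 1 cone-like cell or more 74. Without WT 4M replicate 1 the count was 11 and without replicate 2 it was 10. Of 28 genes that the naming rule took, 5 kept their call with each of 8 libraries left out, all but the sole C198R 4M library: Me3, Cdh12, Akap6, Opn1sw and Cit. The call ended for 22 without WT 4M replicate 1 and for 22 without replicate 2, while their log2 values moved by at most 1.28 and 1.30 times.

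**Figure D3:**
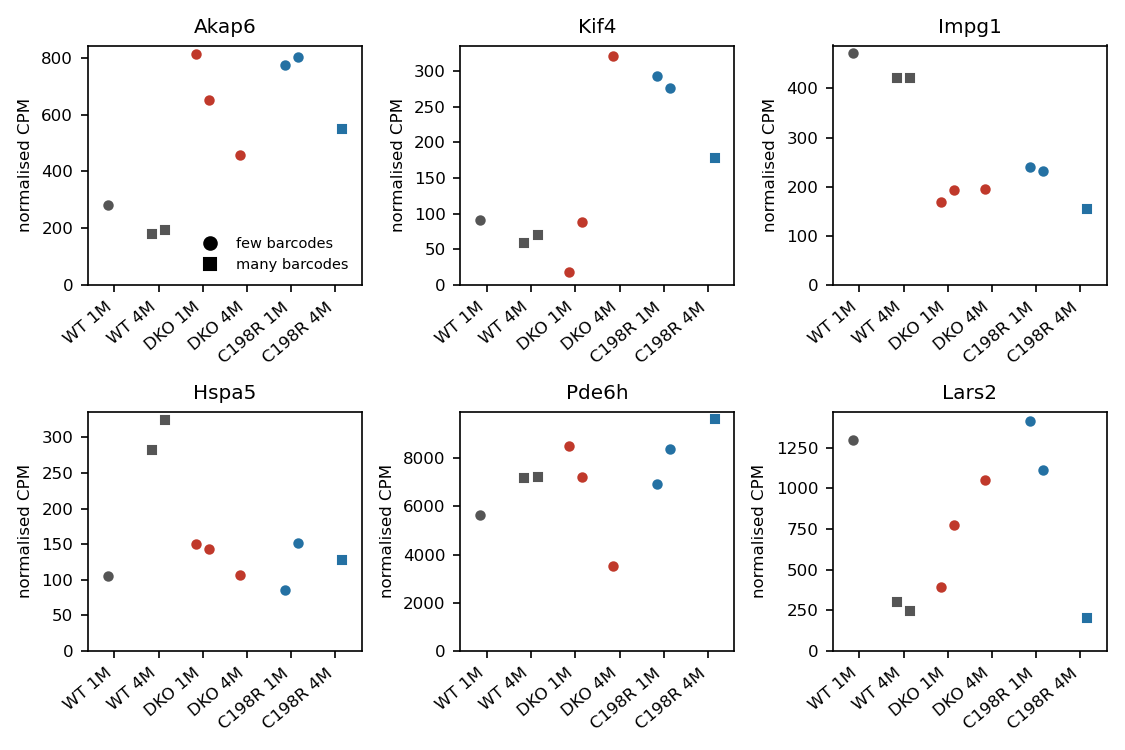
Normalised CPM in cone-like cells for Akap6, Kif4, Impg1, Hspa5, Pde6h and Lars2, 1 point per library in the 9-library fit on a linear axis, by genotype and age, with squares for libraries with many barcodes. Akap6 is higher in mutant than in WT cones at both ages and Impg1 lower in them at 4M; the DKO 4M point for Lars2 is a library with few barcodes beside WT and C198R points from libraries with many.

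Both mutants shared part of these changes. In the same direction against WT, 7 genes were called in both at 1M, 3 that rose and 4 that fell. At 4M 34 were, 21 that rose and 13 that fell, with 1 more called in opposite directions. At both ages the shared genes included Me3 and Akap6, which rose, and Opn1sw, Tmsb10 and Tmlhe, which fell. Shared only at 4M were the rises of Trhde, Rbfox1, Kif4, Lrmda and Gng13 and the falls of Impg1, Hspa5, Cit, Spata6, Ralyl and Osgep, with no test between the ages. Simulated unchanged groups against the same WT libraries shared 0 genes in all 50 runs. Such groups yield few calls, so this cannot gauge lists this long. Independent lists of the observed sizes would share 0.0017 rises and 0.0355 falls at 1M and 0.877 and 0.779 at 4M. The WT libraries are too few to split, so shared controls, and for DKO at 4M the barcode group, may add to the overlap. Without WT 4M replicate 1 the overlap was 4 at 1M and 6 at 4M, without WT 4M replicate 2 it was 6 at 4M, and without DKO 1M replicate 2 it was 3 at 1M.

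The mutants were also set against each other. At 1 month (n = 2 libraries each, all with few barcodes), 4 genes were higher and 13 lower in DKO than in C198R cones. Trhde was higher by 1.44 ± 0.22 log2 (adjusted p = 4.86e-06), Klhl33 by 2.93 ± 0.43 (adjusted p = 2.23e-06), Osgep by 1.40 ± 0.34 (adjusted p = 0.0474) and Lrit3, a synaptic protein of photoreceptors, by 1.29 ± 0.28 (adjusted p = 0.0089). Kif4 fell by 1.89 ± 0.36 (adjusted p = 0.00128), and the rod genes Gnat1 and Cnga1 by 2.68 ± 0.39 and 2.67 ± 0.65. The rod gene list had a median of -1.47 with 3 members lower, 8 adjusted over the list alone (adjusted p = 1.68e-11, adjusted p = 0.628 with an estimated correlation). In Müller glia-like cells its median was -1.49 for the same groups. The mitochondrially encoded list had a median of -0.43, with 0 members called and 5 lower when adjusted over the list alone (adjusted p = 6.71e-18, adjusted p = 0.628 with an estimated correlation). The cone phototransduction list (median -0.03, adjusted p = 0.0325) and the outer segment list (27 members, median -0.17, adjusted p = 0.0414) also pointed down, with 1 and 0 members called. The 1 member was a targeted gene, and without the opsins the former list did not pass (median 0.02, adjusted p = 0.718). Neither was called with an estimated correlation, where the smallest adjusted p = 0.628. With only few-barcode libraries the count of 17 was 9, of which 8 were the same genes. It was 6 to 11 without WT 4M replicate 1 (10), WT 4M replicate 2 (10), DKO 1M replicate 1 (11), DKO 1M replicate 2 (6) or C198R 1M replicate 2 (11), and 27 without C198R 1M replicate 1. Each of the named genes lost its call without DKO 1M replicate 2, Trhde at 1.48, Klhl33 at 2.84, Kif4 at -3.80, and Gnat1 and Cnga1 at fitted values that are no bound. All but Trhde also lost it without C198R 1M replicate 2, Klhl33 at 1.68, Lrit3 at 0.82 and Cnga1 at -0.73. Without either WT 4M library Osgep and Lrit3 lost it, without WT 1M replicate 1 or DKO 1M replicate 1 Osgep and Cnga1, and without C198R 1M replicate 1 Osgep.

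At 4 months (n = 1 library each) 37 genes were higher and 50 lower in DKO than in C198R cones. Klhl33 was higher by 2.64 ± 0.36, Robo2 by 2.36 ± 0.49, Lars2 by 2.35 ± 0.23 and Trhde by 1.95 ± 0.20 (adjusted p = 1.86e-07, 0.0023, 1.09e-12 and 1.33e-11). Arhgap31, S100a1 and Map1lc3a, with 0 counts in DKO, were at least 4.75-fold, 3.60-fold and 3.37-fold lower, and Mab21l1, at 2 counts against 110, had a ratio of 0.131 (95% counting interval 0.0157 to 0.486, adjusted p = 0.0452). The ribosomal protein list had a median of -0.70, with 7 members lower and 35 adjusted over the list alone (adjusted p = 2.19e-25). The nuclear-encoded respiratory chain had a median of -0.47 with 3 lower and 5 adjusted over the list alone (adjusted p = 1.43e-09), and the rod genes had a median of -0.68 with 1 lower and 4 adjusted over the list alone (adjusted p = 2.65e-06). The glycolysis list (median -0.37, adjusted p = 0.00106), the autophagy and lysosome list (16 members, median -0.90, adjusted p = 0.00559) and the antioxidant list (10 members, median -0.56, adjusted p = 0.0211) pointed down as well. So did the cone phototransduction list (median -0.13, adjusted p = 0.000173, adjusted p = 0.00566 without the opsins) and the shared phototransduction list (median -0.13, adjusted p = 0.0223), while the photoreceptor synapse list pointed up (24 members, median 0.27, adjusted p = 0.0223). None of these lists was called with an estimated correlation, where the smallest adjusted p = 0.628. The DKO library had few barcodes and the C198R library many, and the fit with the barcode group as a term called 11 genes, 3 of them among the 87, with S100a1 at 6.16 and Map1lc3a at 6.73 taking the opposite sign. The count was 11 without WT 4M replicate 1, 11 without WT 4M replicate 2, 134 without C198R 1M replicate 1 and 166 without C198R 1M replicate 2. Klhl33, Lars2, Trhde and Arhgap31 kept their call with each of 7 libraries left out, all but the 2 compared, and the other 4 named genes lost it without WT 4M replicate 1 or 2, with log2 values moved by at most 1.05 and 1.04 times.

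The age comparisons asked which cone genes moved from 1 to 4 months. In DKO cones, where both ages had few barcodes (n = 1 library at 4M and 2 at 1M), 5 genes rose and 1 fell. Mdga2, an adhesion protein, rose by 2.69 ± 0.39 log2 (adjusted p = 6.45e-06), Kif4 by 2.09 ± 0.40 (adjusted p = 0.0025) and Ccdc85a by 1.68 ± 0.37 (adjusted p = 0.0244). Lrmda, at 22 counts against 3, rose with a ratio of 12.2 (95% counting interval 3.68 to 63.9, adjusted p = 0.0166). Pde6h fell by 1.15 ± 0.25 (adjusted p = 0.0191). The mitochondrially encoded list had a median of 0.29 (adjusted p = 1.42e-07, adjusted p = 0.631 with an estimated correlation), the nuclear-encoded list -0.19 (adjusted p = 0.00121, adjusted p = 0.631 with an estimated correlation) and the ribosomal list -0.16 (adjusted p = 0.013, adjusted p = 0.837 with an estimated correlation), each with 0 members called over all genes. The autophagy list had a median of -0.75 with 1 member lower when adjusted over the list alone (adjusted p = 0.0166, adjusted p = 0.628 with an estimated correlation). The rod gene list had a median of 0.77, with 1 member rising and, adjusted over the list alone, 7 rising and 1 falling (adjusted p = 0.0114, adjusted p = 0.788 with an estimated correlation). With only few-barcode libraries, 2 of the 6 genes passed, among them Mdga2 at 2.67. Pde6h kept its call with each of 8 libraries left out, all but the sole DKO 4M library. The others lost theirs without DKO 1M replicate 2, Mdga2 at 2.49, Kif4 at 4.00, Lrmda at 2.71 and Ccdc85a at 4.18. Lrmda (3.93) and Ccdc85a (1.43) lost it without DKO 1M replicate 1 as well, and Ccdc85a without WT 4M replicate 1 or 2 (1.78 each).

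In C198R cones 34 genes rose and 35 fell with age (n = 1 and 2 libraries). Rbm3, an RNA-binding protein induced by cold, rose by 1.77 ± 0.40 (adjusted p = 0.00768), Ccdc85a by 1.76 ± 0.35 (adjusted p = 0.00151), the splicing factor gene Srsf7 by 1.61 ± 0.34 (adjusted p = 0.00346), and Hopx by 1.49 ± 0.31 (adjusted p = 0.00255). The orphan receptor gene Gpr158 rose by 2.24 ± 0.57 (adjusted p = 0.0246), Slc24a5 by 2.34 ± 0.57 (adjusted p = 0.0199) and Ldhb by 2.16 ± 0.57 (adjusted p = 0.0383). Cib4, at 83 counts against 3, rose with a ratio of 7.05 (95% counting interval 2.33 to 34.9, adjusted p = 0.0282). Lars2 fell by 2.54 ± 0.19 (adjusted p = 4.46e-18), Cdk8 by 2.12 ± 0.19, Cmss1 by 2.0 ± 0.24 and Camk1d by 1.88 ± 0.22. Dgkh fell by 1.99 ± 0.45, Peak1 by 1.85 ± 0.40, Kazn by 1.62 ± 0.39 and Brd9 by 1.59 ± 0.40. Ribosomal protein genes rose as a list, with a median of 0.51 (adjusted p = 2.58e-21, adjusted p = 0.628 with an estimated correlation). Of them 7 rose, among them Rpl19 by 0.95 ± 0.22 and Rps3a1 by 1.07 ± 0.26, and 31 rose when adjusted over the list alone. The glycolysis list had a median of 0.35, with 2 members rising, Pgam1 by 1.16 ± 0.23 and Ldhb, and 8 rising and 1 falling when adjusted over the list alone (adjusted p = 0.000865, adjusted p = 0.628 with an estimated correlation). In the mitochondrially encoded list mt-Atp8 fell by 1.44 ± 0.25, mt-Nd4l by 0.96 ± 0.22 and mt-Nd3 by 0.78 ± 0.20, the same count of 3 when adjusted over the list alone, with a median of -0.18 (adjusted p = 0.00559, adjusted p = 0.758 with an estimated correlation). The proteasome list (30 members, median 0.35, adjusted p = 0.00759) and the nuclear-encoded respiratory chain (median 0.17, adjusted p = 0.000826) pointed up, each with 0 members called and 1 rising when adjusted over the list alone, and neither was called with an estimated correlation. Rgs9, which speeds the shut-off of phototransduction, fell by 0.76 ± 0.18 and Gsdme rose by 1.05 ± 0.26. Both 1M libraries had few barcodes and the 4M one many. With a barcode term and a minimum of 1 cell, 11 genes were called, 2 among the 69. There Ccdc85a, Srsf7, Kazn, Brd9, Pgam1 and the 4 ribosomal genes named by the rule took the opposite sign, Kazn at 0.96, Brd9 at 1.31, Pgam1 at -2.24 and Rpl19 at -2.44. The count was 9 without WT 4M replicate 1, 9 without WT 4M replicate 2, 38 without C198R 1M replicate 2 and 134 without DKO 1M replicate 1. Lars2, Cdk8, Cmss1 and Camk1d kept their call with each of 8 libraries left out, all but the sole C198R 4M one, and the other 22 named genes lost it without WT 4M replicate 1 or 2, with log2 values moved by at most 1.19 times. Without C198R 1M replicate 2 the call ended for 14 of them, with Cib4 at 0.93, Ldhb at 1.08, Ccdc85a at 0.87, Peak1 at -0.77 and Rps3a1 at 1.79, and Slc24a5 and Gpr158 at fitted values that are no bound. There Rpl19 (1.92), mt-Nd4l (-1.73), Gsdme (4.36) and Hopx (a fitted 10.40) kept it. Without C198R 1M replicate 1 it ended for 7, mt-Nd4l among them at -0.64.

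In WT cones 10 genes rose and 15 fell with age (n = 2 and 1 libraries). Gpr158 rose by 2.55 ± 0.62, the mTOR-activating GTPase gene Rheb by 2.18 ± 0.51 and Lrit1 by 1.86 ± 0.47, and Slc24a5, at 373 counts against 1, had a ratio of 16.1 (95% counting interval 2.87 to 638, adjusted p = 0.0199). Lars2 fell by 2.24 ± 0.20 (adjusted p = 5.4e-15), Cdk8 fell by 2.14 ± 0.18, Kazn by 1.98 ± 0.42 and Cmss1 by 1.95 ± 0.21. Lists that pointed up were the rod genes (median 0.63, 1 member rising and 7 adjusted over the list alone, adjusted p = 2.65e-06), the ribosomal proteins (median 0.42, 0 and 2, adjusted p = 4.48e-11), and the glycolysis list (median 0.44, 1 and 2, adjusted p = 0.00014). So did the nuclear-encoded respiratory chain (median 0.26, adjusted p = 0.000552), the shared phototransduction list (median 0.34, adjusted p = 0.00963), the unfolded protein response (median 0.66, adjusted p = 0.0271) and the heat shock list (median 0.35, adjusted p = 0.0229). None was called with an estimated correlation, where the smallest adjusted p = 0.628. Age and barcode group coincide in WT. The fit with a barcode term called 6 genes, 1 of them among the 25, with Rheb at -1.29, Lrit1 at -0.0535 and Kazn at 0.66 taking the opposite sign. The count was 8 without WT 4M replicate 1, 7 without WT 4M replicate 2 and 43 without C198R 1M replicate 2. Lars2, Cdk8 and Cmss1 kept their call with each of 8 libraries left out, all but the sole WT 1M one, and the other 5 named genes lost it without WT 4M replicate 1 or 2, with log2 values moved by at most 1.13 and 1.11 times.

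The change with age differed between DKO and WT in 17 genes, 14 higher and 3 lower in DKO, or 82.4% higher. With RLE size factors it was 17 higher and 8 lower, or 68%. Pde6h had a difference of -1.51 ± 0.34 log2 (adjusted p = 0.0171), Lars2 of 2.85 ± 0.29 and Cdk8 of 2.78 ± 0.29 (adjusted p = 8.42e-12 for each). Kazn had 3.48 ± 0.72 (adjusted p = 0.00534), Rbfox1 3.33 ± 0.77 (adjusted p = 0.0207) and Mrfap1 -3.33 ± 0.82 (adjusted p = 0.0457), and Map1lc3a, with 0 counts in DKO at 4M, also passed (adjusted p = 0.0457). By list, the differences were lower in DKO for the ribosomal proteins (median -0.50, adjusted p = 5.43e-10), the nuclear-encoded respiratory chain (median -0.39, adjusted p = 2.65e-06), and the shared phototransduction list (median -0.46, adjusted p = 0.00658). The same held for the glycolysis list (median -0.41, adjusted p = 0.00559), the heat shock list (median -0.43, adjusted p = 0.0414) and the autophagy list (median -0.99, adjusted p = 0.0224). The difference was higher in DKO for the mitochondrially encoded list (median 0.34, adjusted p = 2.06e-06). Between C198R and WT no gene's change with age differed in edgeR, where 329 genes had an unadjusted p under 0.05, and DESeq2 also called 0. The unfolded protein response (median -0.59, adjusted p = 0.00737), the rod genes (median -0.48, adjusted p = 0.00737) and the shared phototransduction list (median -0.17, adjusted p = 0.0457) had lower age effects in C198R than in WT. No list of either contrast was called with an estimated correlation, where the smallest adjusted p = 0.628. With a barcode term 2 genes differed between DKO and WT, and Pde6h stood at 2.53 and Map1lc3a at 5.49. The DKO count was 8 without WT 4M replicate 1, 7 without WT 4M replicate 2 and 30 without C198R 1M replicate 2. The C198R count was 1 without C198R 1M replicate 1. Lars2 and Cdk8 kept their call with each of 7 libraries left out, all but the sole WT 1M and DKO 4M ones. The other 5 named genes lost it without WT 4M replicate 2, Pde6h at -1.53 and Kazn at 3.27, and without replicate 1 all of these but Kazn, Pde6h at -1.55. Without DKO 1M replicate 2 Kazn, Rbfox1, Map1lc3a and Mrfap1 lost it, Kazn at 3.41, Rbfox1 at 2.27 and Mrfap1 at -2.70.

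To address which cone genes held or rose with age in the mutants, 1285 genes enriched in cone-like over rod-like cells were chosen from WT libraries, and 893 of them could be tested. In DKO 4 rose (Mdga2, Lrmda, Ccdc85a and Kif4), 1 fell (Pde6h) and 888 did not pass, with the same counts adjusted over the list alone. The 95% interval lay within 2-fold either way for 161 of the 893, so smaller changes stay open there. In C198R, whose ages differ in barcode group, 10 rose and 9 fell, or 15 and 13 adjusted over the list alone. Of its intervals 312 lay within 2-fold. In WT 2 rose and 3 fell. The difference from the WT age effect passed for 4 cone-enriched genes upward and 1 downward, Pde6h, in DKO, and for 0 in C198R by edgeR. Opn1mw had an age effect of 0.68 ± 0.24 in DKO (adjusted p = 0.634) and 0.20 ± 0.21 in C198R (adjusted p = 0.808). Without DKO 1M replicate 1 the number rising in DKO was 2 and without replicate 2 it was 0. In C198R the numbers rising and falling were 0 and 1 without WT 4M replicate 1, 0 and 0 without WT 4M replicate 2 and at most 16 and 15 with another library left out.

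Across all cone contrasts, 62 of 242 list tests were called and 0 were called with an estimated correlation. The lists never called were retinoid metabolism (smallest adjusted p = 0.169), photoreceptor transcription factors (0.0865), immediate early genes (0.258), cell death (0.255), interferon and antigen presentation (0.202), Müller glia genes (0.182) and sex-linked genes (0.301). Fits without a group's sole library ran fewer tests: 38 of 132 were called without WT 1M replicate 1, 30 of 154 without DKO 4M replicate 1 and 36 of 147 without C198R 4M replicate 2, against 37, 33 and 39 of the same tests with all 9 libraries.

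Few rod genes were called except in DKO at 4M, with 6% to 12% of simulated 2-fold changes found. Of 9958 genes, 7 rose and 1 fell in DKO and 4 rose in C198R at 1M (n = 2 libraries per group). At 4M 176 rose and 115 fell in DKO, and 10 rose and 3 fell in C198R. Trhde passed in all 4 comparisons, rising by 7.04 ± 0.45 log2 in DKO and 5.91 ± 0.45 in C198R at 1M and by 5.98 ± 0.36 and 4.96 ± 0.36 at 4M (adjusted p = 9.12e-06, 7.6e-05, 5.34e-06 and 4.45e-05). In DKO at 4M mt-Atp8 rose by 2.74 ± 0.51, Hddc3 by 2.54 ± 0.38 and Lars2 by 2.31 ± 0.39, and Dpp10 fell by 3.99 ± 0.76, Zc3h12b by 2.49 ± 0.56, St6galnac5 by 2.22 ± 0.36 and Ppp3cc by 1.97 ± 0.48. Within libraries of few barcodes 6 genes passed for DKO and 4 for C198R at 1M, with Trhde at 7.0 and 5.88. Within those of many, with 1 C198R library against 2 of WT, Trhde stood at 5.11 for C198R at 4M. DKO and WT at 4M fell in different barcode groups, and with a term for it 1 gene was called, with Trhde at 6.36 and Dpp10 reversed at 6.74. That term left 4 and 7 genes called for DKO at 1M and C198R at 4M. Most few-barcode rods lay in clusters 0 and 1 (46.5% and 40.5%) and most many-barcode ones in 3, 0 and 4 (27.7%, 27.1% and 25.8%). RLE size factors called 116 genes for DKO at 4M.

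For DKO at 4M the rod count was 6 without WT 4M replicate 1, 6 without WT 4M replicate 2, 10 without DKO 4M replicate 1, 10 without DKO 4M replicate 2, and 23 and 20 without DKO 1M replicates 1 and 2. It was 3357 and 3377 without C198R 1M replicates 1 and 2. For DKO at 1M it ranged from 2 to 17 as each library was left out, and for C198R from 3 to 35 at 1M and from 2 to 30 at 4M. Trhde kept its call in all of these fits, and the other 7 rod genes named for DKO at 4M lost theirs without either WT 4M library or either DKO 4M library, with log2 values moved by at most 1.40 times. Without DKO 1M replicate 1 or 2, 5 of them lost it, and without C198R 4M replicate 1 or 2 it was Ppp3cc.

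Müller glia, the main glia of the retina, changed as well. Of 13553 genes, 48 rose and 69 fell in DKO and 17 rose and 9 fell in C198R at 1M. At 4M 301 rose and 590 fell in DKO and 25 rose and 26 fell in C198R. The groups had n = 2 libraries each, except for C198R 4M with 1. Akap6 rose in glia as in cones, by 2.05 ± 0.27 in DKO (adjusted p = 3.59e-05) and 2.40 ± 0.25 in C198R (adjusted p = 1.65e-06) at 1M and by 1.53 ± 0.18 in C198R at 4M (adjusted p = 1.21e-05). In DKO glia at 4M it did not pass (0.95 ± 0.32, adjusted p = 0.0706). The transcription factor gene Tshz3 rose by 2.23 ± 0.17 in C198R at 1M, 1.05 ± 0.16 in C198R at 4M and 1.67 ± 0.18 in DKO at 4M, and the contactin gene Cntn3 by 2.29 ± 0.34 in DKO and 2.19 ± 0.34 in C198R at 1M. Etnppl fell by 2.67 ± 0.22 in DKO at 1M (adjusted p = 2.81e-08) and by 2.52 ± 0.24 at 4M (adjusted p = 1.61e-07), and Npsr1 by 2.83 ± 0.28 at 1M. In DKO at 4M Tsix rose by 2.12 ± 0.20, and Trim12a, at 0 counts against 820, was at least 19.5-fold lower (adjusted p = 1.26e-05). In C198R at 4M Adamts19 fell by 2.24 ± 0.29 and Pde10a fell by 2.06 ± 0.38. Within a batch 115 genes passed for DKO at 1M, 24 for C198R at 1M and 68 for C198R at 4M, with Akap6 at 2.07, 2.43 and 1.53, and DKO at 4M had no value within a batch. Without WT 1M replicate 1 the DKO count at 1M was 26. For DKO at 4M it was 489 without WT 4M replicate 1, 439 without WT 4M replicate 2 and 193 without DKO 4M replicate 1. For C198R it was 42 at 1M without C198R 1M replicate 1, and at 4M 21 without WT 4M replicate 2 and 82 without C198R 1M replicate 1. Akap6, Npsr1, Etnppl, Tsix, Adamts19 and Pde10a kept each call given here with each library left out, except that for C198R at 4M its sole library could not be. Tshz3 in DKO at 4M (1.31) and Trim12a lost theirs without DKO 4M replicate 1, and Cntn3 in C198R at 1M (2.66) without WT 1M replicate 1.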

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

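The tests of explanations in this part were chosen only after the results were seen, while the fit that gave the differences with age was fixed beforehand. The change from 1 to 4 months in cone-like cells differed between DKO and WT in 17 genes by a test of the difference itself. On the log2 scale the difference was 3.48 for Kazn, 3.33 for Rbfox1, 2.85 for Lars2, 2.78 for Cdk8, -3.33 for Mrfap1 and -1.51 for Pde6h, and for Map1lc3a, with 0 counts in DKO at 4M, the fitted -9.40 depends on the prior count and is no bound. Only Lars2 and Cdk8 of these passed with each of 7 libraries left out, all but the sole WT 1M and DKO 4M ones.

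Lars2, Cmss1, Camk1d, Cdk8, AY036118 and Gm42418, chosen after their values were seen, moved together: their median age effect was -2.04 in WT and -2.03 in C198R but 0.61 in DKO cones, so that DKO stood above WT at 4M by a median of 1.51. An age effect shared by the genotypes stays open. The median difference of 2.66 between the DKO and WT age effects only restates the pattern, because age and barcode group coincide in WT. With a term for the barcode group it was 2.76 in cones, with 6 of 6 genes above 2 SE and 2 passing, but in rods it went from 2.13 to 0.59, with 0 of 6 genes above 2 SE. The median of -1.02 for DKO against WT at 1M, all of few barcodes, rests on 1 WT library, so a DKO effect at both ages stays open. Over all barcodes each few-barcode library exceeded each many-barcode one in CPM of all 6 genes. In rod-like cells C198R 4M replicate 1, with few barcodes, exceeded replicate 2 of the same group, with many, in 6 of 6 genes, by a median of 1.43. In rods mean log2 CPM over these genes was at most 9.93 with many barcodes and at least 10.96 with few. With the barcode term the median for DKO minus WT at 4M went from 2.09 to 0.50 in rods, but from 1.51 to 1.98 in cones. In cones the median SE rose from 0.21 to 0.70 and 1 of 6 genes passed instead of 6, Lars2 going from 1.94 ± 0.20 to 2.34 ± 0.82. That cone fit used a minimum of 1 cell and is bridged by 5 cells of 1 library. The pattern may follow the barcode group, which cannot be told apart here from opsin loss at 4 months.

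2 signals lie in cells that no comparison used. Horizontal-like cells made up 58.5% of C198R 4M replicate 1, 103 of 176 cells, above the highest WT library at 0.494%, with a median of 582 UMIs in those cells. Lens-like cells made up 3.78% of C198R 1M replicate 2, 77 of 2035 cells, above the highest WT library at 0.683%. So were 3 DKO libraries, DKO 4M replicate 1 at 2.27% and DKO 1M replicates 1 and 2 at 1.15% and 1.65%.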

How the results depend on the processing

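Fits within a barcode group or with a term for it, and the cone phototransduction list without the opsins, were chosen only after the data were seen, and all other alternatives before. Counts of changed genes moved with almost every choice. Named genes reversed only under the barcode term, and the cone share difference reversed elsewhere. Of 3729 values of 194 named-gene results, 2834 kept direction and side of the threshold, 863 kept direction only, 0 newly passed and 32 reversed, all under the barcode term. Keeping doublets, clustering with all variable genes or at Leiden resolution 2 moved no count by over 1.5 times, and RLE size factors kept 192 of 194 named genes past the threshold. Depth limits the 1M and DKO comparisons, since 1 cone sum held as few as 49239 UMIs, and 3 residual degrees of freedom carry the spread of the cone fit. Where a result moved, the cause was not tested, except that leaving out libraries or cells lowers the number of samples. Below, cone counts are numbers of genes changed.

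With RLE size factors, cone counts were 30 for DKO minus C198R at 1M, 140 at 4M, 41 for age in WT and 131 for age in C198R. With them 17 cone-enriched genes fell with age in C198R, and 116 genes changed in rods for DKO at 4M. With DESeq2 the cone counts were 2 for DKO and 2 for C198R against WT at 1M, 19 and 4 at 4M, 1 and 6 for DKO minus C198R at 1M and 4M, 5, 1 and 5 for age in WT, DKO and C198R, and 5 for the DKO minus WT age effect. The overlap was 1 at 1M and 2 at 4M. DESeq2 called 814 rod genes for DKO at 4M, and in Müller glia 65 and 454 for DKO at 1M and 4M and 17 for C198R at 4M. With no filter on low counts, cone counts were 86 for DKO minus WT at 4M, 45 for DKO minus C198R at 4M, 37 for age in C198R and 9 for the DKO minus WT age effect. Rod counts were then 30 and 1787 for DKO at 1M and 4M and 37 and 48 for C198R, and Müller counts 225 for DKO at 1M and 89 and 113 for C198R at 1M and 4M.

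The labels number replicates 1 and 2 in each group, and deviations of same-numbered libraries correlated from -0.67 to 0.41 over 15 pairs of groups, 3 over 0.1 and 6 under -0.1, so the numbers do not pair the libraries. With a replicate block, cone counts were 49 for DKO and 32 for C198R against WT at 4M, 12 for DKO minus C198R at 4M, 10 and 15 for age in WT and C198R and 10 for the DKO minus WT age effect. Of cone-enriched genes 2 rose in DKO, 3 rose and 0 fell in C198R. The overlap at 4M was 11, and rod counts at 4M were 21 for DKO and 6 for C198R.

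With a barcode term and a minimum of 1 cell, cone counts were 15 and 10 for DKO minus WT at 1M and 4M, 91 for C198R minus WT at 4M, 8 and 11 for DKO minus C198R at 1M and 4M, 6, 0 and 11 for age in WT, DKO and C198R, and 2 for the DKO minus WT age effect. Rod counts were then 4 and 1 for DKO at 1M and 4M and 7 for C198R at 4M. Reversed for DKO minus WT at 4M, in log2, were Map1lc3a (6.74), S100a1 (6.68), Pde6h (3.06), Pdc (0.25), Aipl1 (0.26), mt-Atp8 (-0.21), Uqcrh (0.41), Pgam1 (2.33), Pkm (0.63), Aldoa (1.01), Rpl9 (1.70), Rpl10a (8.92), Rps2 (2.0), Rps3 (9.05) and Gngt1 (1.46). Reversed for DKO minus C198R at 4M were S100a1 (6.16) and Map1lc3a (6.73), and for age in WT Rheb (-1.29), Lrit1 (-0.0535) and Kazn (0.66). For age in C198R they were Ccdc85a (-7.97), Srsf7 (-7.90), Kazn (0.96), Brd9 (1.31), Pgam1 (-2.24), Rpl19 (-2.44), Rps3a1 (-9.09), Rps2 (-1.94) and Rpl9 (-1.94). For the DKO minus WT age effect Map1lc3a (5.49) and Pde6h (2.53) reversed, and in rods Dpp10 (6.74) for DKO at 4M. That fit is bridged by a library of 5 cone-like cells, so its values for genes of few counts are no bounds. With only the libraries of few barcodes, cone counts were 9 for DKO and 5 for C198R against WT at 1M, 9 for DKO minus C198R at 1M and 2 for age in DKO, and the cone-like shares reversed to 0.854 points for DKO and 0.891 for C198R. With only those of many barcodes, 504 cone genes and 3323 rod genes changed for C198R at 4M.

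With the rod gene ratio as a covariate, cone counts were 10 and 4 for DKO minus WT at 1M and 4M, 2 and 11 for C198R minus WT, 1 for DKO minus C198R at 4M, 0 and 2 for age in WT and C198R, and 1 for the DKO minus WT age effect. Then 1 cone-enriched gene rose and 0 fell in DKO, and 1 rose and 0 fell in C198R. With at least 30 cone-like cells per library, cone counts were 104 and 437 for DKO minus WT at 1M and 4M, 96 and 493 for C198R minus WT, and 72 and 436 for DKO minus C198R. They were 173, 48 and 308 for age in WT, DKO and C198R, and 126 and 22 for the DKO and C198R minus WT age effects. With a minimum of 1 cell and no barcode term, they were 10 and 34, 6 and 74, 4 and 19, 15, 0 and 15, and 7 for the DKO minus WT age effect. Without a maximum on mitochondrial UMIs they were 48 for DKO and 33 for C198R against WT at 1M, 34 for DKO minus C198R at 1M, 63 and 11 for age in WT and DKO, and 35 and 11 for the DKO and C198R minus WT age effects, and the C198R share difference reversed to 0.0372 points. As a share of photoreceptor-like cells that difference reversed to 2.55 points. Above 2 log2 in the choice of cone-enriched genes, 5 fell in C198R. With an estimated inter-gene correlation 0 lists were called.

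With each library left out in turn, where the comparison could still be run, cone counts ranged from 13 to 39 for DKO minus WT at 1M and 16 to 197 at 4M, 5 to 13 and 10 to 223 for C198R minus WT. They ranged from 6 to 27 and 11 to 166 for DKO minus C198R, 7 to 43 for age in WT, 9 to 134 for age in C198R, 7 to 30 for the DKO and 0 to 1 for the C198R minus WT age effect. The count for age in DKO stayed within 4 to 9. The overlap ranged from 3 to 7 at 1M and 6 to 43 at 4M and the lists called from 57 to 63 where all 11 contrasts could be run. Where 6, 7 and 7 could, they were 38, 30 and 36, against 37, 33 and 39 of the same tests with all libraries. Cone-enriched genes ranged from 0 to 4 rising in DKO, 0 to 16 rising in C198R and 0 to 15 falling in C198R, and the C198R share difference ranged from -1.10 to 0.422 points. Rod counts ranged from 2 to 17 and 6 to 3377 for DKO at 1M and 4M and from 3 to 35 and 2 to 30 for C198R. Müller counts ranged from 26 to 148 and 193 to 955 for DKO and from 18 to 42 and 21 to 82 for C198R. Named genes kept direction in all 1676 values, which naming by separated groups largely ensures, and 330 no longer passed.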

Other observations

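The tests of explanations in this part were chosen only after the results were seen. Further changes were called in Müller glia-like cells. Against WT at 1M, DKO glia gained the RNA-binding protein gene Rbpms (1.66 ± 0.26 log2 ± SE, adjusted p = 0.000511) and Ppp1r3c, a glycogen-targeting phosphatase subunit (1.47 ± 0.26, adjusted p = 0.00211), and lost vitronectin, Vtn (fell by 1.87 ± 0.34, adjusted p = 0.00273), and the rod gene Nr2e3 (fell by 2.08 ± 0.34, adjusted p = 0.000899). At 4M Cmtm5 rose by 1.66 ± 0.25 in DKO glia and by 1.19 ± 0.18 in C198R glia (adjusted p = 8.49e-05 and 0.000466). Ramac fell by 3.36 ± 0.44 in DKO and Ano1 by 1.19 ± 0.21 in C198R. At 1M Syt1 rose in C198R by 1.64 ± 0.26 (adjusted p = 0.00104) and Pde1c fell by 0.87 ± 0.12 (adjusted p = 0.000204). All are from edgeR over 11 libraries, 1 for C198R at 4M and 2 in every other group. Without WT 1M replicate 1 Rbpms (1.70), Ppp1r3c (1.25), Nr2e3 (-1.56) and Vtn (-1.69) did not pass, and Syt1 did at 2.84. Without DKO 1M replicate 2 Ppp1r3c did not pass (1.24), nor did Ramac without DKO 4M replicate 1, where its fitted -10.52 is no bound.

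Genes named in cones were also read in other cells, where differences between cell types were not tested. In DKO glia at 4M, 31 of 36 such genes had the sign they had in cones, and 18 passed with it against 0 with the other sign. Of these Rps2 fell by 1.40 ± 0.16, Pgam1 by 1.40 ± 0.19 and Hspa8 by 1.24 ± 0.16 (adjusted p = 3.45e-06, 2.13e-05 and 1.96e-05), and mt-Atp8 rose by 1.01 ± 0.21 (adjusted p = 0.00225). DKO and WT at 4M lie in different barcode groups. In the other comparisons fewer passed: 4 of 14 with the sign they had in cones and 1 with the other for DKO at 1M, 1 of 10 and 0 for C198R at 1M, 2 of 24 and 0 for C198R at 4M. The 1 was Trhde, which fell by 0.85 ± 0.17 in DKO glia at 1M (adjusted p = 0.00575). In rods for DKO at 4M only 13 of 32 had the sign they had in cones, of which 8 passed. None passed with the other sign, where Rpl9 had 0.93 ± 0.36 and Rpl10a 1.05 ± 0.39 (adjusted p = 0.104 and 0.0906). Arhgap31 fell in DKO glia, by 1.82 ± 0.21 at 1M (adjusted p = 8.22e-06) and by 2.36 ± 0.35 at 4M (adjusted p = 6.20e-05), the latter not passing without DKO 4M replicate 1 (-2.04). Hspa5 fell in DKO glia at 4M by 0.75 ± 0.16 (adjusted p = 0.00518), while in C198R glia its value was -0.26 ± 0.13 (adjusted p = 0.989) and in DKO rods 0.64 ± 0.29 (adjusted p = 0.144). Me3, which rose in cones, had -0.37 ± 0.15 in DKO glia at 4M (adjusted p = 0.152).

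A set of 34 genes besides Opn1sw was called in the same direction in DKO and C198R cones. Passenger sequence around the targeted opsins is argued against as the main cause of the set. Of 33 genes with a location 0 lay within 20 Mb of Opn1sw or Opn1mw (upper 95% limit 10.6%, against 1.69% of all tested genes), and Tmlhe was unplaced. A background difference that acts in other cell types may account for part: 17.9% of those tested in Müller glia, 5 of 28 (95% interval 6.06% to 36.9%), changed there in the same direction in both mutants at an unadjusted p under 0.05, against 3.45% of all genes. Of them Akap6 passed at 1M after adjustment in both mutants, with 2.05 in DKO and 2.40 in C198R. So did Gm8797 at 1M (4.10 and 4.31) and 4M (3.63 and 4.65), and Gm12248 (5.10 and 4.70) and Magi1 (1.05 and 0.75) at 4M. In rods it was 5 of 25 at the same unadjusted limit, against 2.26%, with Trhde, Gm8797 and Gm12248 passing after adjustment too. Since the libraries of a genotype share their background, this explanation stays open. A response of cones to the loss of opsin, which the design names, was not tested and stays open too.

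By the median over 15 rod genes, -1.47, these were lower in DKO than in C198R cone-like cells at 1M. Their share of all cone UMIs differed little, 1.14% and 1.02% in the DKO libraries against 1.04% and 1.21% in the C198R ones, while in glia it was 0.0975% and 0.148% against 0.259% and 0.346%. Free rod RNA in the droplets is a candidate explanation that passed its test: in Müller glia-like cells, which do not express them, the median was -1.49 and 14 of 15 genes had the same sign, with Gnat1 at -1.54. A change of rod genes within cones was not tested apart from it.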
